A study of Drosophila melanogaster with 22 samples.

How the data were processed

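The data came from Drosophila larvae that lacked the endogenous cluster of replication-dependent histone genes and lived on a transgenic histone array. The array carried either wild-type histone genes (HWT) or genes in which lysine 9 of histone H3 was changed to arginine (K9R). Per the labels' protocols, mutant larvae were picked by a fluorescent marker and collected as newly wandering larvae of the third instar. The series held 22 samples. Open chromatin was measured by FAIRE-seq (formaldehyde-assisted isolation of regulatory elements, which recovers DNA that is poorly crosslinked to protein) in wing imaginal discs, in 3 K9R and 2 HWT samples. Genomic DNA inputs of the FAIRE extracts made up 2 K9R and 2 HWT samples. Stranded, ribosome-depleted total RNA was sequenced from wing discs in 3 K9R and 3 HWT samples. HP1a, the protein that binds methylated H3 lysine 9, was measured by ChIP-seq in nuclei of whole larvae, in 3 K9R and 2 HWT samples with 1 input per genotype. Each FAIRE sample pooled 50 discs, each RNA sample 40 discs and each HP1a sample 50 larvae, per the labels' protocols. The HP1a chromatin received 2.5% of Drosophila virilis chromatin as a spike-in. No label ties samples of a genotype to separate crosses, so p-values measure the spread between these pools.

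Per the submitters' processing notes, the reads were processed with Bowtie2, MACS2, bedtools, edgeR, TopHat, Cufflinks and DESeq2 on the dm6 build. The notes give no version and no role for each tool. The FAIRE table held 24025 peaks with a median width of 421 bp and 1 value per library. These deposited FAIRE values are a signal: counts that the authors had adjusted to a common size, no longer whole numbers, from which whole reads could not be recovered. They summed to between 6695190 and 7207963 per library, so the true depth is unknown. The same table gave the authors' log2 fold change, log2 average level and unadjusted p-value, per the file headers. Its fold change ran from K9R to HWT (correlation 0.9999 with the library columns) and was turned here to K9R over HWT.

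The HP1a table covered 139675 windows of 1 kb and gave only the authors' comparison: a log2 fold change, a log2 average CPM and a p-value, per the file headers. Its direction is not named and was read as K9R over HWT, because its values fell where FAIRE signal rose. The linear averages summed to far more than values scaled to the table's own totals can, so the library sizes behind them were not totals of these windows, and whether the spike-in entered the scaling is not given in the sources used here. The deposited RNA table listed 11823 assembled loci by position, without names or strand. For each it gave a mean count over libraries divided by size factors (a signal), a log2 fold change and its standard error, a test score (the fold change divided by its error), a p-value and an adjusted p-value, per the file headers, which match DESeq2's column names. The direction of the RNA comparison is also not named. It was read as K9R over HWT because RNA and FAIRE changes went together in pericentromeric DNA (Spearman rho 0.30 over 363 loci), and it rests on that relation alone. Elsewhere rho was -0.05 on the autosomal arms, 0.01 on the X arm, 0.14 on chromosome 4, -0.19 on Y and -0.15 on unplaced scaffolds, and it was 0.04 over all 7570 loci. All statements of direction for HP1a and RNA rest on these readings. A fold change was present for 11638 loci, a p-value for 10722 and an adjusted p for 8986. A further 916 loci had a fold change and no p-value. The reason is not given, and without values per library their fold changes may rest on a single library.

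For the genomic DNA, the authors deposited a count per FAIRE peak and the same count as RPM (scaled by library reads). The table used here covered 3195 of the 3984 peaks of arm 2L, from position 1144 to 18488398, and 1 incomplete last line was left out. The remaining peaks were not analysed here. Library sizes recovered from the ratio of count to RPM were 2396015 and 2708433 reads for K9R and 1326856 and 2126646 for HWT. The median peak held 12, 14, 7 and 11 reads, so copy number of single peaks was measured coarsely.

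The planned FAIRE test was edgeR if the table held counts, or the authors' comparison if it held nothing else. The table held that comparison and adjusted, non-whole values per library, which the plan did not cover. The test was therefore chosen after the table was seen: limma (version 3.58.1) with a trended prior on log2(value + 1), with Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale, which understates changes of weak peaks. For HP1a the authors' p-values were adjusted by the Benjamini-Hochberg method, and for RNA their adjusted p-values were used at 0.05 with no test added. Genomic DNA counts were tested with edgeR's quasi-likelihood test (version 4.0.16) with trimmed-mean scaling. Statistics were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and in R 4.3.3. Plots were drawn with matplotlib 3.10.9.

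Genome regions, gene lists and the rule for named items were fixed before the data were examined. The plan held the euchromatic arms as a single region, and their split into autosomal arms and X arm was a departure from it. Pericentromeric DNA was 2L from 22 Mb, 2R up to 5.4 Mb, 3L from 23 Mb, 3R up to 4.6 Mb and X from 22 Mb. Chromosomes 4 and Y stood alone, unplaced scaffolds formed 1 class, and the rest of the arms was the euchromatic part. The unplaced class includes scaffolds assigned to Y without a position on it, so it is not separate from Y sequence. Region medians were tested by 10000 circular shifts of the values along the genome, two-sided, with adjustment over 18 region tests, where the smallest possible p is 1e-04. Each test compares a median with the mean of its shifted medians, which include other regions, and not with 0. Counts of calls were compared by Fisher's exact test, two-sided. Neighbouring peaks, windows and loci are not independent, so Fisher p-values are too small. FAIRE and HP1a changes were compared across peaks, through the 1 kb window over each peak centre (7 relations). RNA and FAIRE changes were compared across loci with a peak inside them or within 1 kb of an end, since strand is unknown (10 tests).

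RNA loci were annotated with RefSeq gene spans of the same build. A locus took a gene's name when it was the only coding gene, or else the only gene, with at least 50% of its span inside the locus. This named 7258 loci, while 2845 coding loci held several coding genes and kept no name. The 27 gene lists were tested with cameraPR in limma on the authors' test score, with a preset correlation of 0.01. All 11638 loci with a fold change entered these tests, also the 916 without a p-value. An estimated correlation needs values per library and was not possible. RNA named genes were the 8 largest rises and 8 largest falls past the threshold with a mean count of at least 50, plus the 2 genes of smallest p in each direction per list, or the gene of smallest p in a list without calls. For FAIRE and HP1a the 5 sites of smallest adjusted p in each direction, at least 50 kb apart, were named. Distances to genes run from the centre of a peak or window.

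On simulated FAIRE values for 24025 peaks, the limma test recovered 56 of 100 peaks changed 2-fold and 15 of 100 changed 1.5-fold, with 0 unchanged peaks called. The simulation changed far fewer peaks than were called in the data and drew noise independently per library, so these rates need not carry over. For the genomic DNA, 120 of 200 simulated 4-fold changes were recovered among 3195 peaks, with 3 unchanged peaks called. The list test gave p under 0.05 for 18 of 500 random lists and recovered 100 of 100 planted ones. The shift test called 5 of 100 null series. Alternatives covered thresholds, minimum folds, level filters, other scalings, region boundaries, overlap rules, a replicate block and leaving out each library.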

Results

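The question addressed was what happens to heterochromatin when lysine 9 of the replication-dependent histone H3 is replaced by arginine. Chromatin accessibility (24025 FAIRE peaks), HP1a occupancy (139675 windows of 1 kb), RNA (11823 assembled loci) and genomic DNA coverage were compared between larvae living on K9R histone arrays and larvae living on HWT arrays. All coordinates are in dm6 and counted from 1.

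In wing discs, chromatin opened across the DNA next to the centromeres in K9R. FAIRE signal was higher in K9R at 2353 of 2690 pericentromeric peaks (87.5%) and lower at 6 of them. The median pericentromeric peak carried 162.5 ± 5.01 normalized counts in K9R (SD, n = 3) and 70.5 ± 4.09 in HWT (SD, n = 2), a 2.31-fold difference between the group means. The autosomal arms stayed close to their HWT level, with medians of 183.2 ± 2.72 normalized counts in K9R (n = 3) and 186.8 ± 3.91 in HWT (n = 2). Over the genome, limma called 4528 peaks higher and 989 lower in K9R at an adjusted p of 0.05.

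The opening was seen on every large arm. The median log2 fold change of pericentromeric peaks was 1.54 on 3L (501 of 556 peaks higher), 1.24 on 2R (1020 of 1086), 1.24 on 3R (454 of 598), 1.11 on X (261 of 296) and 1.07 on 2L (117 of 154). Together these peaks had a median log2 fold change of 1.26 (circular-shift permutation p = 0.0018, adjusted p = 0.00648). Among unplaced scaffolds, which are largely repeat-rich sequence, 624 of 925 peaks were higher and 2 were lower, with a median log2 fold change of 0.76. On chromosome Y, which is almost entirely heterochromatic, 111 of 201 peaks were higher and 0 were lower, with a median of 0.75. The shift tests of these last medians did not pass the threshold (adjusted p = 0.150 for unplaced scaffolds and 0.161 for Y, permutation). Their shifted medians include opened pericentromeric DNA, which limits these tests.

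Chromosome 4, a small chromosome on which active genes lie within HP1a-rich chromatin, changed little in its typical peak. Its median peak held 224.5 ± 5.66 normalized counts in K9R (n = 3) and 191.9 ± 5.09 in HWT (n = 2), and its median log2 fold change was 0.14. The circular-shift permutation (p = 0.9995) does not test this median against 0. Its shifted medians ran from -0.157 to 1.793, as they include other opened DNA. Some of its peaks did open: 39 of 98 were higher and 8 lower, an odds ratio of 9.83 against the autosomal arms for the higher calls (Fisher's exact p = 2.01e-21). On the autosomal arms 1107 of 17572 peaks were higher and 918 lower, and on the X arm 294 of 2539 were higher and 55 lower.

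Single sites gave larger changes than the region medians. The site of smallest p was at positions 1 to 1346 of the scaffold Un_DS484689v1, with 4328 ± 362 normalized counts in K9R (n = 3) and 516 ± 20.1 in HWT (n = 2), a log2 fold change of 3.06 (limma adjusted p = 4.03e-08). Pericentromeric peaks at X 23381089 to 23381417, 272922 bp from the nearest coding gene ATbp, and at 2R 678511 to 679313 inside DIP-lambda, a cell surface protein of the immunoglobulin family, rose by 3.28 and 2.66. A peak inside CG43366 at 2R 5906550 to 5907932, in the arm just beyond the pericentromeric boundary, rose by 2.90, from 102.1 ± 1.73 to 771.8 ± 57.8 normalized counts. The scaffold Un_DS484068v1 rose by 3.03 at positions 311 to 484.

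The named sites that closed had smaller fold changes and lay in the arms. A peak at 2R 13565557 to 13566431, 4601 bp from CG42807, went from 769.1 ± 3.96 to 357.5 ± 4.87 normalized counts, a log2 fold change of -1.10. The peak over an end of CG6118 at 3R 15434546 to 15435343 had a log2 fold change of -1.23. Peaks near dpn, a neural stem cell repressor of the Hes family (2R 8233439 to 8234771), near shd, the enzyme that makes active ecdysone (3L 14613990 to 14614634), and over Mondo and Gr39a (2L 21296351 to 21297032) changed by -0.81, -0.92 and -0.92. These 10 sites had standard errors between 0.0748 and 0.100 on the log2 scale.

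**Figure D1:**
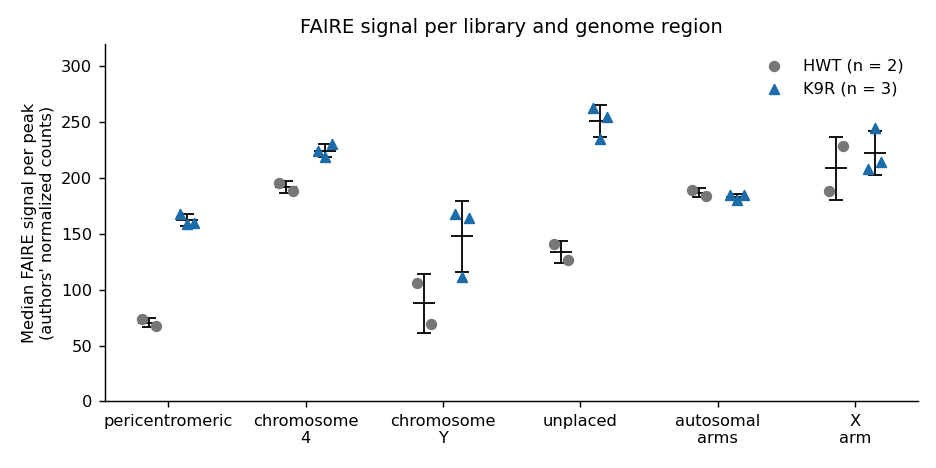
Median FAIRE signal per peak (y axis, the authors' normalized counts) in each library, by genome region (x axis); circles are HWT (n = 2), triangles K9R (n = 3), horizontal marks the group mean and bars the SD. Every K9R library lay above both HWT libraries in pericentromeric DNA, on chromosomes 4 and Y and on unplaced scaffolds, while on the autosomal arms and the X arm the ranges of the genotypes overlapped.

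With 3 libraries against 2, an exact permutation test of the library medians that doubles the smaller tail cannot go below p = 0.2, and one on absolute differences cannot go below 0.1. Pericentromeric DNA, chromosome 4 and unplaced scaffolds reached both values. Replicate 2 of each genotype had a higher X median and a lower Y median than its fellows. The Y median was 0.62 of the arm median in K9R replicate 2 against 0.91 and 0.89 in the others, and 0.38 against 0.56 in HWT. Without both replicates numbered 2, a choice made after the values were seen, 4617 peaks were higher and 899 lower, 116 of 201 Y peaks were higher, and the X arm had 397 higher and 42 lower. The balance of calls depended on scaling: 82.1% of the main calls were higher, against 55.3% (3135 higher, 2531 lower) after quantile normalization, which moved the median of all peaks from -0.01 to -0.12. Under that scaling the pericentromeric median was 0.80 while the medians of chromosome 4 (-0.06) and the X arm (-0.05) changed sign. The autosomal arm median moved as well, from -0.06 to -0.18, so these sign changes reflect in part the shift of all peaks. The lower calls also depended on single libraries, with 401 without HWT replicate 2, 487 without HWT replicate 1, 549 without K9R replicate 3 and 609 without K9R replicate 1.

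Genomic DNA was compared to ask whether copy number could differ between the genotypes at the same peaks. Over the 3195 peaks of 2L analysed here, edgeR's quasi-likelihood test called 0 of 2242 tested peaks at an adjusted p of 0.05 (81 had an unadjusted p under 0.05, and 0 of 2298 were called when libraries were scaled by their totals). The 199 of these peaks with higher FAIRE signal in K9R had a median log2 FAIRE change of 0.95 and a median genomic DNA change of 0.07, which was 0.03 without HWT replicate 1 and 0.12 without HWT replicate 2. At the 93 peaks that opened at least 2-fold the values were 1.53 and 0.05. Over all 199 peaks, subtracting each peak's genomic DNA ratio took the median FAIRE change from 0.95 to 0.88. The part of 2L covered does not reach its pericentromeric DNA, so copy number there was not analysed here.

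HP1a, in the direction read here, was lost from the same kinds of DNA in whole larvae. In the authors' deposited table, 15305 of 17947 pericentromeric windows (85.3%) had lower HP1a in K9R and 103 had higher HP1a, with a median log2 change of -0.92. The authors' deposited table also gave lower HP1a at 1177 of 1319 windows of chromosome 4 (median -1.05), 1565 of 1768 of chromosome Y (-1.10) and 4059 of 4520 on unplaced scaffolds (-1.15). Across the genome, 27179 windows of the authors' deposited table were lower and 8230 higher after Benjamini-Hochberg adjustment of its p-values. Chromosome 4 and pericentromeric DNA thus had similar HP1a medians in the authors' deposited table, with FAIRE medians in wing discs of 0.14 and 1.26.

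The loss varied along the genome. For pericentromeric windows of the authors' deposited table, the median was -1.06 on 2L, -0.97 on 2R, -1.03 on 3L and -0.84 on 3R, but -0.30 on X, where 586 of 1476 windows were lower. On the autosomal arms the authors' deposited table gave 4099 windows higher and 3900 lower with a median of 0.07, and on the X arm 4013 higher and 1173 lower with a median of 0.19. At an adjusted p of 0.01 the counts of the authors' deposited table were 1286 higher and 2625 lower on the autosomal arms, and 1983 and 858 on the X arm, so the balance on the arms depends on the threshold. Circular shifts of the values in the authors' deposited table gave an adjusted p of 0.0171 for pericentromeric windows, 0.0018 for unplaced scaffolds, 0.106 for chromosome 4 and 0.0888 for Y (permutation). Restricted to windows in the upper 10% of mean level, the pericentromeric median of the authors' deposited table was -1.14 and its shift p was 0.190. Of these windows 6293 were pericentromeric and 4766 on the autosomal arms. Many shifted windows thus also lost HP1a, and this test cannot decide.

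The losses of smallest adjusted p in the authors' deposited table were on Y at 860001 to 861000 (log2 change -3.40), on the scaffolds Un_DS485504v1 (-3.03) and Un_CP007088v1 (-2.59), on 2R at 5106001 to 5107000 near gus (-1.34), and on X at 21713001 to 21714000. This last window lay inside flam, a source of piRNAs that silence transposons in somatic ovary cells, and changed by -2.29 in the authors' deposited table. Among the gains of smallest adjusted p in the authors' deposited table, HP1a rose by 1.34 over CtsL1, a lysosomal protease gene (2R 13967001 to 13968000), by 1.16 over l(3)mbn (3L 6125001 to 6126000) and by 1.22 over CG12480 (X 14170001 to 14171000). The authors' deposited table also listed gains of 1.13 over Myc, a growth regulator (X 3384001 to 3385000), and of 0.59 at 2R 5049001 to 5050000, 15736 bp from TpnC41C. The table gave no value per library, so these changes carry no SD.

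**Figure D2:**
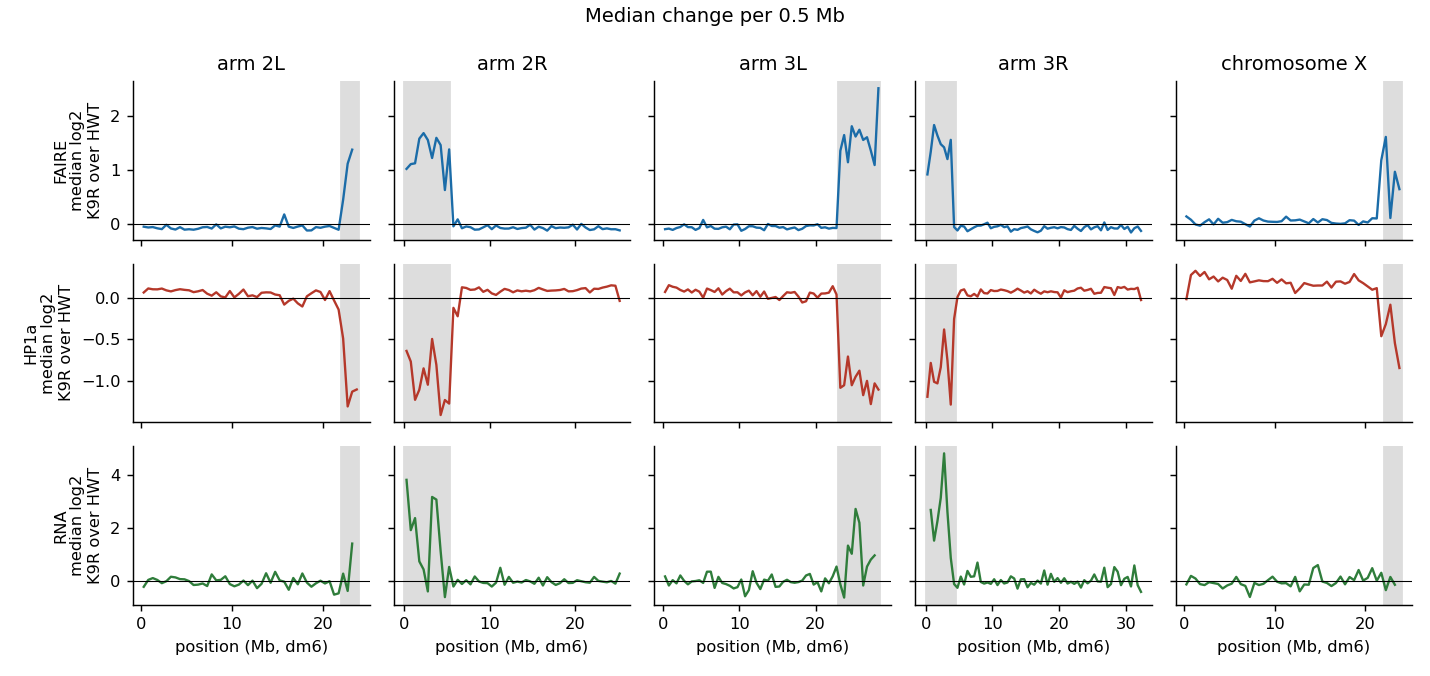
Median log2 fold change, K9R over HWT, in steps of 0.5 Mb (y axis; lines) along the 5 large chromosome arms (x axis, Mb in dm6) for FAIRE peaks, HP1a windows and RNA loci; grey marks pericentromeric DNA, and HP1a and RNA values are from the authors' deposited tables. FAIRE medians lay above 0 and HP1a medians below 0 in 37 of 38 steps within the grey parts and in 7 of 230 steps outside them. The largest FAIRE change outside was on X next to the boundary (FAIRE 1.18, HP1a -0.46).

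Peaks that opened mostly lay in windows where HP1a changed in 1 direction, read here as lower. FAIRE came from wing discs and HP1a from whole larvae, so these changes were not measured in the same cells. Of the 4528 FAIRE-higher peaks, 3540 (78.2%) had a window with lower HP1a and 87 (1.92%) one with higher HP1a in the authors' deposited table, against 847 (4.35%) and 1908 (9.79%) of 19487 other peaks. Which direction is the loss follows from how the table was read and not from these counts. The overlap was also present on the autosomal arms, where 523 of 1107 opened peaks (47.2%) had lower and 18 higher HP1a in the authors' deposited table, against 197 and 1212 of 16465 others. In pericentromeric DNA, where most windows were lower, the shares with lower HP1a were 2159 of 2353 (91.8%) and 216 of 337 (64.1%) with the authors' deposited table (Fisher's exact p = 2.86e-37).

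The sizes of the changes in FAIRE and in the authors' deposited table were related across all peaks, with a sign that restates the reading of direction (Spearman rho -0.44, Pearson r -0.62; p = 1e-04 for both by circular-shift permutation, the smallest these can give, adjusted p = 1.40e-04 over 7 relations). The relation had the same sign on the autosomal arms (rho -0.19, permutation adjusted p = 1.40e-04) and the X arm (rho -0.29). Within pericentromeric DNA the sizes showed no detectable relation (rho -0.06, permutation p = 0.312), nor did those of chromosome 4 (rho -0.24, p = 0.103). On Y (rho 0.40) and unplaced scaffolds (rho 0.33) the relation had the other sign, a contrast that does not depend on the reading. Y held 201 peaks, unplaced scaffolds 915 and the X arm 2539, and a region has fewer distinct shifts than peaks. The draws outnumbered these shifts, so the permutation p of 1e-04 obtained for these regions lies below what their shifts can give. The adjusted p of 1.40e-04 given above rests in part on those values and is therefore too small. All these relations are correlations across peaks, which are not independent replicates. They also set wing discs (FAIRE) against whole larvae (HP1a), so they do not show how the changes relate within 1 tissue.

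The manipulated genes were checked first in the RNA. The histone repeat on 2L (21416953 to 21538720) held 103 assembled loci, copies of 5 genes. All 23 copies of His2B were lower in K9R in the authors' deposited table (median log2 change -0.84, median standard error 0.22), as were 18 of 22 copies of His4 (between -1.11 and -0.60, median standard error 0.30). The 15 copies of His3, the gene that carries the substitution, had a median of -0.86 with a standard error of 0.50 in the authors' deposited table, and 0 of them passed the threshold. None of the 23 His1 copies (median -0.52) or 20 His2A copies (-0.43) in the authors' deposited table was called. The larvae lacked this endogenous cluster, so reads placed on its near-identical reference copies are attributed to the transgenic array. The copies share these reads, so they do not count as separate genes or separate K9R from HWT transcripts. Their values do not show transcription of endogenous histone genes.

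RNA from heterochromatin rose in the direction read here. Among 8986 loci with an adjusted p in the authors' deposited table, 992 were higher and 172 lower in K9R, and 131 of the lower loci lay outside the histone repeat. Pericentromeric DNA held 361 higher and 24 lower loci of 937 in the authors' deposited table, with a median log2 change of 1.02 (odds ratio 12 for a rise against the autosomal arms, Fisher's exact p = 4.83e-165). On chromosome Y the authors' deposited table gave 67 of 77 loci higher and 0 lower, with a median of 3.77, and on unplaced scaffolds 172 of 286 higher and 1 lower, with a median of 2.85. By circular-shift permutation of the authors' deposited table, the adjusted p was 0.0244 for Y, 0.0036 for unplaced scaffolds and 0.0643 for pericentromeric DNA, which therefore missed the threshold by that test. The pericentromeric median of the authors' deposited table was 0.14 at loci at or above the median mean count (permutation p = 0.0155), 0.65 with boundaries 0.5 Mb toward the telomeres and 1.35 with boundaries 0.5 Mb toward the centromeres. That of unplaced scaffolds in the authors' deposited table was 1.37 at or above the median mean count.

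**Figure D3:**
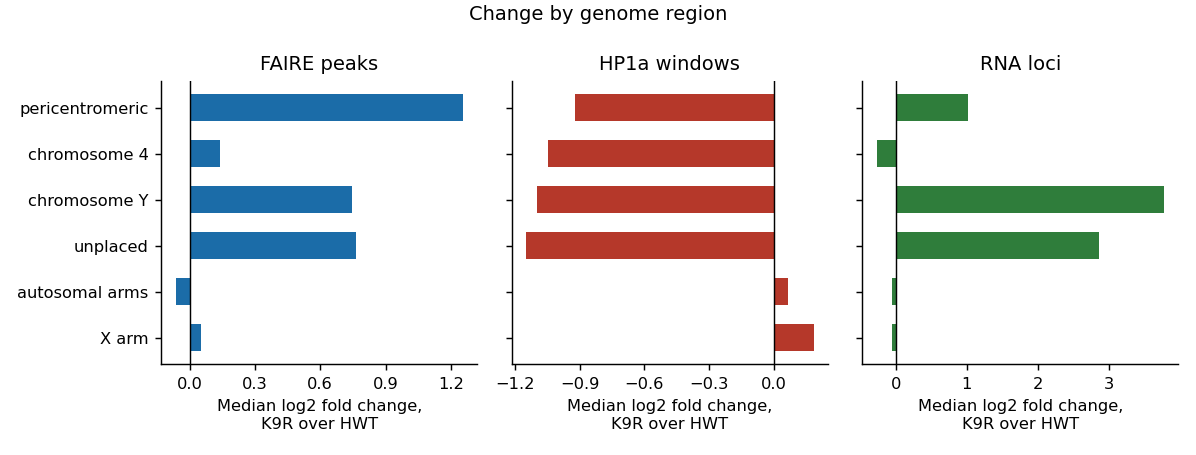
Median log2 fold change, K9R over HWT (x axes, bars), of FAIRE peaks, HP1a windows and RNA loci in 6 genome regions (y axis); HP1a and RNA values are from the authors' deposited tables and each panel has its own scale. Chromosome 4 had an HP1a median of -1.05 in whole larvae, and FAIRE and RNA medians of 0.14 and -0.27 in wing discs. Pericentromeric DNA had 1.26 (FAIRE), -0.92 (HP1a) and 1.02 (RNA).

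Pericentromeric loci without an annotated gene rose about as often as all pericentromeric loci (38.0% against 38.5% higher), and coding loci rose less often. In the authors' deposited table, 227 of 598 loci without an annotated gene were higher against 26 of 161 coding loci (odds ratio 3.18, Fisher's exact p = 6.23e-08). A further 93 of 142 pericentromeric loci of the authors' deposited table that cover part of a gene were higher. Chosen after their values were seen, for their high mean counts, the locus at 2R 3762532 to 3776337 (mean 58432) had a log2 change of 6.62 ± 0.53 (SE) and that at 3L 26764668 to 26878066 (mean 56928) one of 3.72 ± 0.32 in the authors' deposited table. By arm, the pericentromeric medians of the authors' deposited table were 1.86 on 3R, 1.20 on 2R, 0.79 on 3L, 0.41 on 2L and -0.16 on X.

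Genes that normally reside in pericentromeric DNA went both ways. Coding loci there were higher in the authors' deposited table more often than on the autosomal arms without the histone repeat (26 of 161 against 303 of 5782, odds ratio 3.48, Fisher's exact p = 5.90e-07). They were also lower more often in the authors' deposited table (10 of 161 against 77 of 5782, odds ratio 4.91, p = 1.07e-04). Among 16 measured genes of the fixed pericentromeric list, the authors' deposited table had Maf1, a repressor of RNA polymerase III, higher by 2.17 ± 0.18 (SE) and Snap25, a synaptic fusion protein, by 1.18 ± 0.37. Cht10, a chitinase, changed in the authors' deposited table by -1.77 ± 0.20 and nrm, a cell adhesion gene, by -1.11 ± 0.40, and the other 12 did not pass. FAIRE signal over Cht10 rose by 2.31 and over Maf1 by 1.42. The list as a whole had a median of -0.29 in the authors' deposited table (3 higher and 2 lower adjusted over the list alone, cameraPR adjusted p = 0.271, or 0.0438 with the rank-based test).

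Chromosome 4 genes changed little as a group: 2 of 17 rose in the authors' deposited table, 2 fell and 13 did not pass (4 and 3 adjusted over the list alone, cameraPR adjusted p = 0.724). The neuronal transcription factor onecut rose by 2.30 ± 0.64 (SE) and the glutamate receptor mGluR by 1.35 ± 0.34 in the authors' deposited table. The eye selector toy changed by -1.78 ± 0.62 and Sox102F by -0.63 ± 0.23 in the authors' deposited table. Of 4 measured Y genes, the authors' deposited table had ORY higher by 5.98 ± 0.59 and Ppr-Y by 1.58 ± 0.39, while kl-2 and FDY had 0.24 ± 0.37 and -0.93 ± 0.63 (2 higher adjusted over the list alone, cameraPR adjusted p = 0.192).

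RNA changes in 1 direction, read here as rises, coincided with opened chromatin. Of 1128 loci with a FAIRE-higher peak, 237 (21%) were higher and 19 lower in the authors' deposited table, against 215 (4.58%) and 62 of 4694 loci with unchanged peaks (for higher, odds ratio 5.54, Fisher's exact p = 3.13e-61, adjusted p = 3.13e-60 over 10 tests). In pericentromeric DNA, from which the direction was read, the higher counts from the authors' deposited table were 145 of 260 against 11 of 65 (odds ratio 6.19, adjusted p = 5.78e-08) and the lower ones 10 against 2. Higher counts from the authors' deposited table on the autosomal arms were 55 of 689 against 126 of 3875 (odds ratio 2.58, adjusted p = 3.50e-07), and lower ones 8 (1.16%) against 48 (1.24%). The sizes of the changes over all autosomal arm loci ran slightly the other way with the authors' deposited table (rho -0.05 over 6081 loci, circular-shift permutation p = 9.00e-04). Loci with a FAIRE-lower peak were lower in the authors' deposited table in 26 of 535 cases against 62 of 4694 (odds ratio 3.82, adjusted p = 8.21e-07). On unplaced scaffolds the relation ran the other way in the authors' deposited table, with 24 of 47 against 31 of 39 (odds ratio 0.27, adjusted p = 0.00917), as on Y with 3 of 6 against 26 of 26 (adjusted p = 0.00672 by Fisher's exact test). When only peaks within 1 kb of a locus end were used, the odds ratio for the autosomal arms was 1.26 with the authors' deposited table (p = 0.353).

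Among the largest rises of named genes, CG42650 rose by 7.87 ± 0.67 (SE) in the authors' deposited table, the olfactory receptor gene Ir84a by 7.78 ± 0.68, CG18605 by 6.35 ± 0.37, betaNACtes6, a member of a testis-specific family, by 6.08 ± 0.62, and CG42300 by 5.87 ± 0.43. Rises of 5.73 ± 1.04 for Ubc84D and 5.49 ± 1.07 for nxf4 were also listed in the authors' deposited table. CG42650, Ir84a, Ubc84D and nxf4 lie in 1 stretch of 3R (7346730 to 7519456) in which 14 of 22 loci were higher in the authors' deposited table, 10 of them with nearly equal mean counts (133.7 to 140.7). Among 12 measured testis genes of the authors' deposited table, 3 rose, Mst84Db (named after its value was seen, 3.73), Mst84Dc (3.82) and Mst84Dd (3.74), all in the same stretch, and 9 did not pass (3 adjusted over the list alone, cameraPR adjusted p = 0.428).

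Falls were smaller. CG4009 changed by -4.20 ± 1.13 (SE) in the authors' deposited table, CG13053 by -2.77 ± 0.57, Blimp-1, a transcriptional repressor of the ecdysone response, by -2.18 ± 0.58, and CG15905 by -2.17 ± 0.26. The pericentromeric genes CG41284 and CG17698 changed by -2.07 ± 0.57 and -1.93 ± 0.38 in the authors' deposited table, ImpE2, an ecdysone-inducible disc gene, by -2.01 ± 0.36 and CG15046 by -1.86 ± 0.34. Among 8 measured ecdysone response genes of the authors' deposited table, ImpE2 and ImpE1 (-1.25 ± 0.46) fell, Eip63E rose (1.16 ± 0.42) and 5 did not pass (2 lower and 1 higher adjusted over the list alone, cameraPR adjusted p = 0.428). The loci of Eip63E (4 genes), grim (3 genes) and Snap25, Ppr-Y, Syt1 and Act57B (2 genes each) also hold non-coding genes, so their changes are not separable from those.

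Of the 27 gene lists, 4 shifted by cameraPR. Larval muscle markers rose in 10 of 11 cases in the authors' deposited table (10 adjusted over the list alone, median log2 change 3.05, adjusted p = 1.09e-06), among them Mhc, the muscle myosin heavy chain (4.18 ± 0.73, SE), and TpnC47D, a troponin C (4.72 ± 0.87). Cuticle genes rose in 7 of 20 cases in the authors' deposited table (10 adjusted over the list alone, median 1.79, adjusted p = 0.00892), including TwdlM (5.43 ± 1.10) and Cpr62Bc (4.72 ± 1.07), both structural proteins of the exoskeleton. Wing disc patterning genes shifted down in the authors' deposited table (median -0.39, adjusted p = 0.00892), although B-H1, a homeobox gene of the notum (-0.72 ± 0.26), was the only 1 of 21 to pass and 0 passed adjusted over the list alone. The germline list also shifted down in the authors' deposited table (median -0.88, adjusted p = 0.0381) with 0 calls among 2 tested genes, 0 adjusted over the list alone, and a smallest p of 0.132 for bol (0.47 ± 0.31). The oocyte patterning gene osk (-5.30 ± 1.11), Pxt (-4.21 ± 1.12) and swa (-3.63 ± 1.11), named after their values were seen, had no p-value in the authors' deposited table. Their scores still entered the list test, so the germline shift rests in part on genes for which the authors gave no p-value. Restricted to loci at or above the median mean count, only the muscle list passed (adjusted p = 1.17e-06), and cuticle (0.197), wing patterning (0.160) and germline (0.179) did not, with the authors' deposited table.

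**Figure D4:**
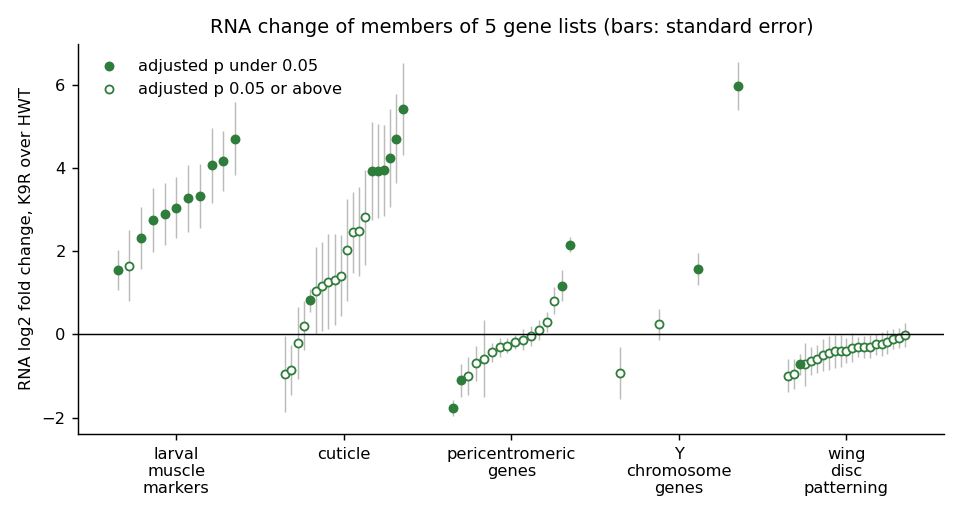
Log2 fold change of RNA, K9R over HWT (y axis; points with standard errors), for the members with an adjusted p of 5 gene lists (x axis), from the authors' deposited table; filled points have an adjusted p under 0.05. All 11 larval muscle genes lie above 0, whereas the 21 wing disc patterning genes lie at or below 0 and 1 of them is filled.

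Few markers of other tissues and cell types passed singly, although many lay above 0 in the authors' deposited table: 13 of 13 salivary gland and gut, 7 of 8 hemocyte and 5 of 6 neuron and glia markers. With the rank-based test the authors' deposited table gave adjusted p = 0.0163 for salivary gland and gut and 0.0438 for hemocyte markers. Against arm loci as background, the adjusted p from the authors' deposited table was 0.0467, 0.00505 and 0.00968 for the 3 lists in that order. Restricted to loci at or above the median mean count, the 3 lists did not pass (cameraPR adjusted p = 0.319, 0.160 and 0.163). PPO2, a crystal cell phenoloxidase, was the 1 of 7 hemocyte markers to rise in the authors' deposited table (3.99 ± 0.87, SE; 2 adjusted over the list alone, list adjusted p = 0.159). Syt1, a synaptic vesicle protein, was the 1 of 5 neuron and glia markers to rise in the authors' deposited table (1.19 ± 0.21; 3 over the list alone, p = 0.183). Act57B, an actin of larval muscle, was the 1 of 7 muscle precursor markers to rise (3.24 ± 0.80; 1 over the list alone, p = 0.643) in the authors' deposited table. The tracheal marker pio changed by -0.73 ± 0.25, the 1 of 6 to fall in the authors' deposited table (1 over the list alone, limma cameraPR adjusted p = 0.191). The authors' deposited table had 0 calls, also over the list alone, among 3 fat body markers (Lsp1beta 1.72 ± 1.03, list p = 0.643) and 12 salivary gland and gut markers (betaTry 2.0 ± 1.08, list p = 0.283). Of 2 measured sex and dosage compensation genes, roX2, a non-coding RNA of the male X chromosome, fell by 1.63 ± 0.57 in the authors' deposited table (1 over the list alone, list p = 0.191). The other p-values in this paragraph are cameraPR values adjusted over lists.

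The regulators of heterochromatin that could be measured were not called singly, but their list shifted down under some tests. Of 23 genes on the H3K9 list, 9 lay on a locus of their own. The gene of HP1a itself was not among them. None of 7 measured genes for H3K9 methylation and HP1 proteins passed in the authors' deposited table, also over the list alone (median -0.58, adjusted p = 0.0702), although all 9 with a fold change lay below 0; wde, a partner of an H3K9 methyltransferase, had the smallest p at -0.99 ± 0.42 (SE). Among Polycomb and trithorax genes the authors' deposited table had 0 calls of 7, also over the list alone (adjusted p = 0.191; Su(z)2 -0.55 ± 0.29). Of variant histones 0 of 2 passed in the authors' deposited table, but both were lower adjusted over the list alone (adjusted p = 0.159; His4r -1.57 ± 0.69). Of 3 piRNA pathway genes 0 passed, also over the list alone (adjusted p = 0.549; BoYb 2.11 ± 0.88, authors' deposited table). Of 7 Hox genes pb rose by 0.75 ± 0.22 in the authors' deposited table (1 over the list alone, adjusted p = 0.271). These p-values of lists are cameraPR values. With the rank-based test the adjusted p from the authors' deposited table was 0.00194 for the H3K9 list, 0.0345 for Polycomb and trithorax (7 of 7 below 0), 0.0260 for variant histones (3 of 3 below 0) and 0.0345 for Hox genes (7 of 7 above 0). Against arm loci as background it was 0.00909 for the H3K9 list, 0.0283 for variant histones, 0.0467 for Hox genes and 0.0621 for Polycomb and trithorax. Restricted to loci at or above the median mean count, none of these lists passed by cameraPR. The adjusted p was then 0.270 for the H3K9 list, 0.436 for Polycomb and trithorax, 0.319 for variant histones and 0.3615 for Hox genes.

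Stress and growth lists showed few calls. The repressor chinmo, tied to regeneration and growth, was the 1 of 6 JNK and wound genes to rise in the authors' deposited table (1.08 ± 0.38, SE; 2 higher and 1 lower over the list alone, cameraPR adjusted p = 0.982). The small heat shock gene Hsp23 changed by -1.27 ± 0.35, the 1 call among 10 stress genes of the authors' deposited table (1 over the list alone, cameraPR adjusted p = 0.643). The authors' deposited table had 0 calls, also over the list alone, among 4 immune genes (pirk 1.06 ± 0.85), 10 apoptosis and DNA damage genes (grim 2.13 ± 1.03), 11 cell cycle genes (CycB -0.56 ± 0.38) and 54 ribosomal protein genes (RpL21 -0.40 ± 0.21). Their cameraPR adjusted p-values were 0.450, 0.450, 0.234 and 0.487 (cell cycle 0.0447, downward, with all loci that hold a list gene). All 9 immune genes with a fold change in the authors' deposited table lay above 0 (adjusted p = 0.0439 with the rank-based test). Median, mean and test differed in sign in the authors' deposited table for the lists of chromosome 4, JNK, apoptosis, muscle precursor and ribosomal protein genes.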

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

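Added after the data were seen were the alternatives with a pseudocount of 10, arm centring, quantile normalization, the authors' p-values, both FAIRE libraries numbered 2 left out, all loci holding a list gene, arm loci as background, 1 locus per run of near-equal neighbours, and 1 locus per histone gene. By region, some counts moved by more than 1.5 times at a threshold of 0.01. Among them, the autosomal arms held 189 higher RNA loci (324 in the main result) and 311 lower FAIRE peaks (918). Genome-wide counts of calls kept to within 1.5 times their main value except as follows, and the cause was not tested. A threshold of 0.01 gave 107 lower RNA loci (172 in the main result), 342 lower FAIRE peaks (989) and 3342 higher HP1a windows (8230). Requiring at least a 2-fold change gave 86 lower RNA loci, 2855 higher (4528) and 4 lower FAIRE peaks, and 13 higher and 12941 lower HP1a windows (27179). Keeping loci, peaks or windows at or above the median level gave 421 higher RNA loci (992), 1618 higher FAIRE peaks, and 5363 higher and 13956 lower HP1a windows, fewer features being tested. Lower FAIRE peaks numbered 594 with arm centring and 2531 with quantile normalization. Leaving out each FAIRE library gave 401 to 1067 lower and 4142 to 4531 higher peaks, where a lone HWT library was assumed to vary like the others. In the upper 10% of HP1a level the pericentromeric median was -1.14 (permutation p = 0.190, a test that cannot decide there because many shifted windows also lost HP1a). Gene lists past the threshold numbered 12 with the rank-based test, 1 at or above the median level and 10 with arm loci as background (4 in the main result). Directions turned for the HP1a median of the autosomal arms (-0.016) and the RNA median of the arms (0.0025) when the euchromatic median was subtracted, for HP1a on the X arm in the upper 10% of level (-0.25), and for FAIRE against HP1a in pericentromeric DNA at or above the median level (rho 0.046). The turns under subtraction follow from the centring, which puts arm medians near 0, and do not test the direction. Of 146 values of single regions, relations and lists under alternatives, 100 kept their direction and side of the threshold, 16 moved by more, 18 passed the threshold where the main value did not, 8 ceased to pass it, and 4 changed sign. Values with the euchromatic median subtracted are counted among them. That subtraction cannot change a shift test beyond its random draws, so those values say nothing about robustness. With 1 locus per run, 979 RNA loci were higher, and with 1 locus per histone gene 133 were lower. Using the authors' FAIRE p-values, 4525 peaks were higher and 666 lower, 5096 of them shared with the main result in the same direction.

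The FAIRE libraries share only the numbers 1 and 2, and no label makes a number a batch. Deviations of equally numbered libraries correlated at 0.432, and a fit with the replicate block called 4849 peaks higher and 1383 lower, 5378 of them as in the main result. For RNA, HP1a and genomic DNA no paired analysis was possible because the RNA and HP1a tables hold no values per library and the genomic DNA groups share only the number 2. For lack of such values, leaving out libraries was not run for RNA and HP1a. DESeq2 tests and size factors, trimmed-mean scaling and count filters were not run for FAIRE, HP1a and RNA, whose tables hold no whole counts, and neither was a list test with an estimated correlation. Genomic DNA depth, at 7 to 14 reads per median peak, limits copy number at single peaks.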

Other observations

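The tests on roX2, on coding and other Y loci and on accessibility at Y loci, the eggshell list, the muscle and cuticle loci without a FAIRE peak, the neighbour pairs outside the stretch of 3R, the intervals described first and the zone of 2 Mb were chosen after the results were seen. The interval on 2R between Pld and jing (6255267 to 6502005) holds a large germline piRNA cluster, a stretch of transposon remnants, and behaved like heterochromatin although it lies outside the pericentromeric boundary. FAIRE signal was higher at 39 of its 51 peaks (median log2 change 0.79), and HP1a was lower at 174 of its 235 windows in the authors' deposited table (median -0.60). RNA in the authors' deposited table was split along the interval. The parts were cut by the sign of the RNA change, the middle running from the first to the last locus below 0, so the flanks hold none below 0. Of the 18 flank loci 11 were called higher in the authors' deposited table, with rises of 5.43 ± 0.28 (SE) at 6297412 to 6302274 and of 3.71 ± 0.21 at 6417396 to 6443767. Of the 9 loci of the middle part, 6308019 to 6353300, 3 were called lower in the authors' deposited table, one by -2.78 ± 0.43 at 6338821 to 6344607. In this middle part 11 of 12 FAIRE peaks were higher (median 0.88), and 35 of 45 HP1a windows were lower (median -0.65, authors' deposited table). The flam locus on X (21631891 to 21790731) opened at 26 of 31 peaks (median 1.43) and lost HP1a at 140 of 160 windows of the authors' deposited table (median -0.72), yet 2 of its 12 RNA loci were called higher in the authors' deposited table (0.96 ± 0.31 and 2.87 ± 0.56).

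Changes near the pericentromeric boundary came in part from this interval. Within 2 Mb of the boundary on the autosomal arms, 11.3% of HP1a windows were lower in the authors' deposited table, and 9.34% without the interval between Pld and jing, against 3.57% in the rest of the arms (odds ratio 2.78 without the interval, Fisher's exact p = 3.15e-102). FAIRE peaks were higher in 9.45% against 5.99%, but without the interval in 109 of 1515 (odds ratio 1.22, Fisher's exact p = 0.0637). RNA loci there, without the histone repeat and the interval, were higher in 5.61% against 4.83% (odds ratio 1.17, p = 0.448) and lower in 2.81% against 1.27% (odds ratio 2.24, p = 0.00917) in the authors' deposited table. Genes of the larval cuticle cluster at 3L 6130386 to 6161589 had high fold changes in the authors' deposited table, up to 6.16 ± 1.06 for Cpr65Ax1 and 6.04 ± 1.04 for Lcp65Ag3, but mostly no p-value.

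RNA rose most on chromosome Y and unplaced scaffolds, a class that includes scaffolds assigned to Y. More male larvae in the K9R pools would raise roX2, a male-specific RNA. In the authors' deposited table roX2 changed by -1.63 ± 0.57 (SE), which argues against that account. However, the female genes Yp1 and Yp2 were also lower (-3.09 ± 1.22 and -2.64 ± 1.23, without p-values). Coding Y loci do not decide it: 3 of 5 with an adjusted p were higher and 0 lower in the authors' deposited table. Their median of 0.37 over 8 loci includes ARY and Pp1-Y2, with mean counts of 1.95 and 0.80. Accessibility gained at the same Y loci was examined on few loci. RNA rose by a median of 1.42 at the 6 loci with an opened peak and 4.72 at the 26 with unchanged peaks (FAIRE medians 1.05 and 0.19), a difference of -3.30 (permutation p = 2.40e-04, authors' deposited table). RNA thus also rose where no peak was called opened. The contrast cannot decide the account: the 6 loci include the coding locus of Ppr-Y, coding Y loci rose less, and neighbouring loci are not independent. Reads of repeated sequence placed on Y remain a candidate explanation: 69 Y loci without a coding gene had a median change of 4.49 and 8 coding ones 0.37, a difference of 4.12 (permutation p = 1.60e-04, authors' deposited table). The coding median has the limits given above. As a hypothesis, repeat transcripts derived from any chromosome may account for part of the rise assigned to Y, and their true origin was not tested.

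Muscle and cuticle RNA was higher in K9R. All 15 eggshell genes with a fold change lay below 0 in the authors' deposited table (median -3.85), for example Cp15 (-4.96 ± 1.15, SE) and Yp1 (-3.09 ± 1.22). Of the 2 with an adjusted p, 1 was called lower (psd, -2.80 ± 0.97), and no list test was run. The other 13 eggshell genes had no p-value, against 903 other loci without and 10720 with one (odds ratio 77.2, Fisher's exact p = 3.72e-13). Whether the falls of those 13 genes hold in every library is therefore unknown. Accessibility gained at the genes is argued against for the 7 of 17 called muscle and cuticle loci that hold a FAIRE peak (median FAIRE change -0.12 ± 0.06, bootstrap SE, 0 opened), but for the other 10, which hold no peak, it cannot be told apart from other causes. Larval muscle in the K9R pools cannot be told apart from a change in disc cells, since 7 further muscle genes had a median of 0.72 ± 0.72 in the authors' deposited table, with Mp20 at 2.56 and the most abundant, Msp300 (mean count 157153), at 0.72. Ovary tissue in a HWT pool also cannot be told apart from other causes, with a median of -1.01 ± 0.64 over 6 oocyte genes in the authors' deposited table (dhd, the most abundant at a mean count of 4230, -2.48, and CycB3, also in the cell cycle list, -0.34). Values per library would decide the questions of tissue.

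Some neighbouring RNA loci had nearly equal mean counts, as in the stretch of 3R with Ir84a and the Mst84D genes. Chance agreement of levels is argued against: 13 neighbouring pairs of loci called higher had means within 2% of each other, while the highest of 1000 shuffles gave 8, and although 5 pairs lie in the stretch that prompted the question, the 8 pairs outside it were matched by 1 of 1000 shuffles. Whether the same reads were counted at neighbouring loci cannot be told apart from other causes, since 28 of 640 loci called higher (4.38%) and 165 of 5275 uncalled loci (3.13%) had such a neighbour (odds ratio 1.42, Fisher's exact p = 0.0987, authors' deposited table). Read-through transcription across the stretch could also give equal levels and was not tested. Keeping 1 locus per run left 979 of the 992 higher loci.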
